A study of Vitis vinifera with 8 samples.

How the data were processed

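Small RNA was sequenced from deseeded berries of the L1 microvine, a dwarf grapevine (Vitis vinifera) that fruits in a growth room. The 8 libraries form 4 groups of 2 biological replicates each, per the series' design text. Pre-véraison berries (5 to 6 weeks after anthesis, before the onset of ripening) and post-véraison berries (12 to 14 weeks) were taken at 16 °C at 9 AM and, after 1 hour at 38 °C, at 10 AM. Temperature therefore goes together with the hour of sampling, and with any step of handling done at each time. Per the labels' protocols, 3 synthetic RNA standards (Std 2, Std 3 and Std 6) were added to the RNA before library construction, and the libraries were made with the Illumina v1.5 small RNA protocol and sequenced single-end.

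The deposited files hold, for each library, distinct read sequences and the count of reads of each, not normalized. Their reads run from 10 to 35 nt. The adapter trimmer, any aligner and any filter are not given in the sources used here. No reference genome was used here, so no read was placed on the grape genome, shares of reads by genome class were not computed, and every item is named by its sequence or by the miRNA family that this sequence is known for. Members of a family that share reads could not be separated beyond their sequence.

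The libraries held from 7038198 to 13760501 reads, 95094702 in all. Reads of the standards were marked by a shared run of 14 nt or an edit distance of at most 3, and made up 7.74% to 20.4% of a library. They were left out of library sizes and tests. The ratio of Std 6 to Std 3 ranged from 7.30 to 15.9 and that of Std 3 to Std 2 from 6.18 to 24.5, so scaling by the standards carries that spread. The remaining reads of 18 to 28 nt, from 4000660 to 9861397 per library, set the library size. CPM are counts per 10 to the power 6 of such reads after TMM scaling, and RPM are the same without TMM. In the pre-véraison 16 °C replicate 1 library, 20.8% of reads were 34 to 35 nt long. Reads were counted without molecular identifiers, so floors given for counts of 0 (3 counts over a group) cover counting error only.

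The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling. All 8 libraries entered one model of 4 group means, which left 4 residual degrees of freedom, and contrasts gave the stage effect averaged over temperature, the heat effect in each stage, the heat effect averaged over stages, and the stage by heat interaction. Sequences of 18 to 28 nt at 2 CPM or more in at least 2 libraries were tested. These were 42870 sequences holding 61.5% of the reads, with a biological coefficient of variation of 0.41. A second table replaced the sequences of listed families by family sums (reads of 18 to 25 nt that begin with the first 18 nt of a listed mature sequence). Of 42 listed families and strands, 39 were tested: 35 of 37 miRNA families and 4 passenger strands, the strand of the duplex that is usually discarded. Families miR827 and miR845 had 0 reads in the joined table, which held sequences with at least 10 reads in total, and tasiR-ARF had 35 reads. Adjusted p-values are Benjamini-Hochberg values over the whole table, with a threshold of 0.05, and standard errors are those of log2 fold changes. Functional lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated one. Length shares and lists of other RNAs were compared by exact permutation tests, 4 against 4, two-sided, over 70 arrangements, with both stages pooled for temperature. The smallest p these can give is 0.0286, and 0.333 for 2 against 2, so within a stage only values are given.

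The family and RNA lists, the tests, their alternatives and the rule for named items were fixed before the data were examined. Fixed families were named whatever their result. Up to 12 further families per comparison were named by smallest adjusted p. Among sequences in no family with non-overlapping groups, up to 5 with the largest rise and 5 with the largest fall were named per comparison. A sequence sharing 16 nt with one already taken in the same comparison and direction was skipped, so similar sequences can be named in different comparisons. The 5′ ends of the 18S and 5.8S rRNA, the reads ending in CCA, 5 runs of 14 nt that mark rRNA and tRNA variants, and 16 miRNAs known from other plant groups were added after the data were seen. Sequences holding such a run are not printed, since they may not be of grape.

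Replicates of a group differed by more than counting error (chi-square per degree of freedom from 7.55 to 33.6), so no 2 files are one library read 2 times. That they are biological and not technical replicates rests on the design text alone. The fit was tested on simulated counts for 42870 features with 50 changed features at each of 4 folds. For the stage comparison, 2% of 2-fold, 46% of 4-fold, 96% of 8-fold and 100% of 16-fold changes were recovered. With so few changed features the adjusted threshold is stricter than in the data, where 17582 sequences passed by stage. These stage shares are therefore not the power of the real stage test. A sequence at a log2 fold change of 0.84 passed that test (adjusted p = 0.0418, edgeR). For heat in pre-véraison berries the shares were 0%, 10%, 56% and 90%, and for heat in post-véraison berries 0%, 0%, 42% and 88%. For heat averaged over stages they were 4%, 50%, 98% and 100%, and for the interaction 0%, 0%, 10% and 36%. False calls were 5 of 127 for stage, 5 of 83 and 4 of 69 for heat in pre-véraison and post-véraison berries, 18 of 144 for heat averaged over stages, and 2 of 25 for the interaction. Changes of 4-fold or less within a stage were thus mostly below what these libraries can show. The alternatives were DESeq2 1.42.0 (size factors and Wald test), total reads without TMM, the standards as library size, other count minimums and lengths, other family matches, the replicate number as a block, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.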

Results

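Small RNA populations of grape berries were compared before and after véraison, the onset of ripening, and before and after 1 hour at 38 °C. Each of the 4 groups of stage and temperature held 2 biological replicates. In the order of replicates 1 and 2, total reads were 7038198 and 12343049 for pre-véraison berries at 16 °C, 13760501 and 13538490 at 38 °C, 8830383 and 13354093 for post-véraison berries at 16 °C, and 13315397 and 12914591 at 38 °C. The comparisons address which small RNAs differ between the stages and which respond to heat, and heat cannot be separated from the hour of sampling in this design.

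The 4 libraries of post-véraison berries held a lower share of 24-nt and higher shares of 21-nt and 22-nt reads than the 4 of pre-véraison berries. Shares of one total depend on each other, so a change in the amount of any length is not shown. In plants, 24-nt RNAs are mostly siRNAs that direct DNA methylation at transposons, and most miRNAs are 21 nt long. The share of 24-nt reads was 38.0% ± 2.25 (SD, n = 4) before and 27.9% ± 2.81 after véraison, and the share of 21-nt reads 27.4% ± 2.23 and 34.5% ± 4.46. The 22-nt share was 6.26% ± 0.318 before and 9.30% ± 1.09 after. In each of these 3 classes the 4 libraries of one stage lay apart from the 4 of the other (exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 can give; adjusted p = 0.0629 over 11 lengths, above 0.05). The 18-nt and 19-nt shares were also higher after véraison with the same p, by 1.25 and 1.45 points. By temperature, no length passed (exact permutation p of 0.514 or more). That test pooled both stages, so the stage difference was part of the spread, and a smaller heat difference could be missed. The 24-nt share was 36.7% ± 1.22 at 16 °C and 39.4% ± 2.45 at 38 °C before véraison (SD, n = 2). After véraison it was 26.6% ± 0.618 and 29.3% ± 3.97, where 38 °C replicate 1 was at 26.5% and replicate 2 at 32.1%.

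**Figure D1:**
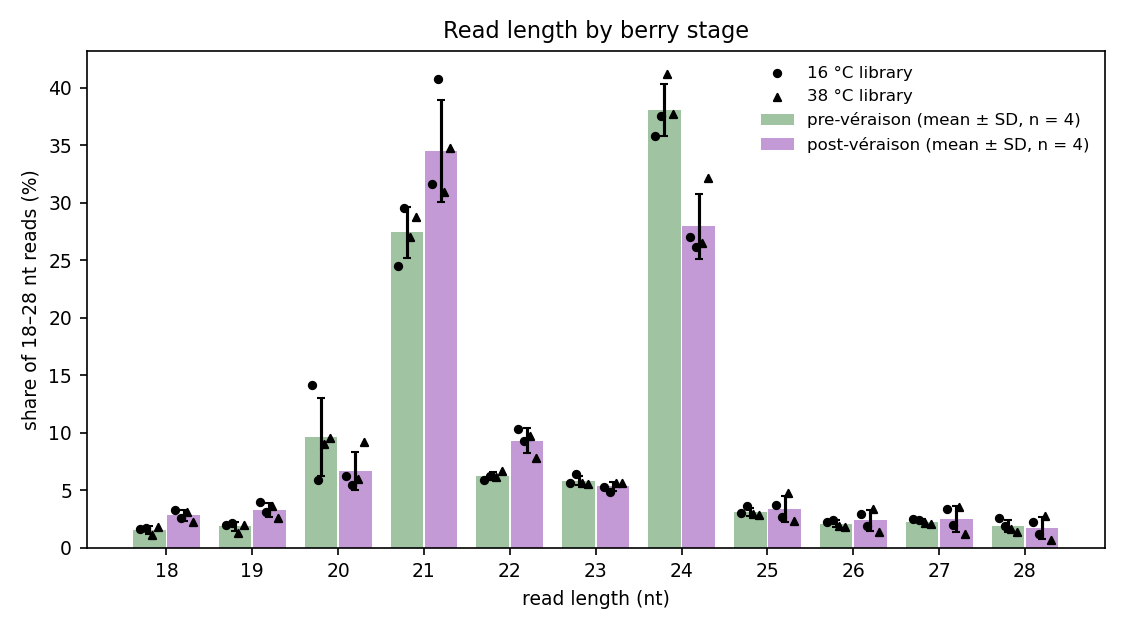
Share of 18 to 28 nt reads (y axis, %) at each read length (x axis, nt) in pre-véraison and post-véraison berries; bars are means of 4 libraries with SD, circles are 16 °C and triangles 38 °C libraries. The 24-nt share is 38.0% before and 27.9% after véraison.

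Listed miRNA families held 4.50% ± 0.455 (SD, n = 4) of the 18 to 28 nt reads before véraison and 4.08% ± 0.361 after it (exact permutation p = 0.143). The most abundant were miR535, at 21135 ± 2340 CPM before and 18738 ± 5534 CPM after, and miR159, at 17724 ± 3202 and 11945 ± 4511 CPM. Neither passed the test between stages, with log2 fold changes of -0.21 ± 0.28 (SE) and -0.59 ± 0.30. Without post-véraison 38 °C replicate 2, miR159 passed it (log2 fold change -0.80, adjusted p = 0.0398 in edgeR's quasi-likelihood test).

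Of 39 families and strands tested between stages, 15 rose and 4 fell after véraison (edgeR quasi-likelihood test, adjusted p under 0.05 over the whole table; also 19 adjusted over the list alone). Of the 35 miRNA families, 14 rose, 3 fell and 18 did not pass. The largest rises were of miR3627, from 1.40 ± 0.776 to 10.98 ± 3.24 CPM (log2 fold change 2.85 ± 0.47 SE, adjusted p = 0.00109; 3.89 without pre-véraison 16 °C replicate 2), and of miR3624, from 39.3 ± 18.7 to 262 ± 65.9 CPM (2.78 ± 0.38). Close behind came miR530, from 4.04 ± 2.65 to 25.4 ± 2.07 CPM (2.78 ± 0.39), and miR403, which targets AGO2, from 30.9 ± 14.4 to 201 ± 72.9 CPM (2.73 ± 0.40). The largest fall was of miR164, which targets NAC transcription factors of the CUC group, from 386 ± 147 to 48.9 ± 69.96 CPM (log2 fold change -3.42 ± 0.62; -4.87 without post-véraison 38 °C replicate 2). The 19 families and strands kept their direction under each of the 3 other scalings, and 11 of them still passed with the standards as library size. Between the stages at 38 °C alone 4 passed, and at 16 °C alone 16, as contrasts within the same model of all libraries. The 38 °C contrast holds post-véraison 38 °C replicate 2, which lay toward the pre-véraison libraries, as described below. Its lower count can therefore not be read as an effect of heat on the stage difference.

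**Figure D2:**
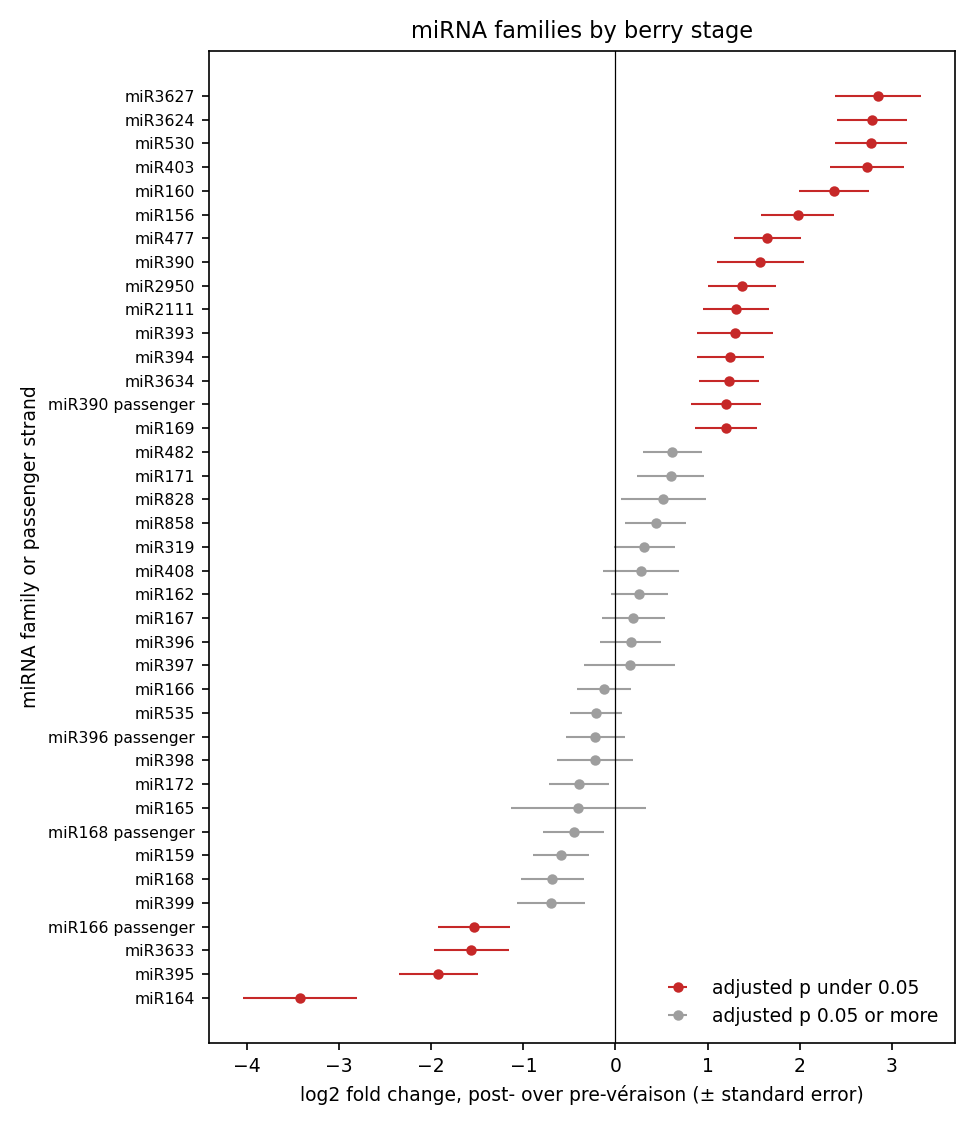
Log2 fold change from pre-véraison to post-véraison berries (x axis) with its standard error for each tested miRNA family or passenger strand (y axis); red points pass the adjusted p of 0.05. Values run from -3.42 for miR164 to 2.85 for miR3627, and 15 families or strands rise while 4 fall.

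Of the 4 tested families of the auxin list, which act on auxin response factors and receptors, 3 rose and none fell: miR160 (from 8.96 ± 3.70 to 45.8 ± 8.24 CPM, log2 fold change 2.38 ± 0.38), miR390 (1.57 ± 0.47) and miR393 (1.30 ± 0.41), while miR167 was at 0.19 ± 0.34. The list's set test gave an adjusted p of 0.0613 at the preset correlation and 0.504 with an estimated correlation.

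In the list of grape and other lineage families, 6 of 7 rose and none fell. Besides miR3627, miR3624 and miR530 these were miR477 (log2 fold change 1.65 ± 0.36), miR2950 (1.37 ± 0.37) and miR3634 (1.23 ± 0.32). With the standards as library size neither passed (adjusted p = 0.109 and 0.117, edgeR). Nor did miR2950 without pre-véraison replicate 2 at 16 °C (0.0631) or at 38 °C (0.0675), or miR3634 without pre-véraison 38 °C replicate 1 (0.0721). The set test gave an adjusted p of 0.000725 at the preset correlation, and 0.213 with an estimated correlation. For all 35 miRNA families together, with a median log2 fold change of 0.44, the adjusted p was 0.0361, and 0.504 with an estimated correlation, 0.0536 with the replicate number as a block and 0.105 without post-véraison 38 °C replicate 2.

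Of the development timing list, miR156, which targets SPL transcription factors and marks juvenile phase in plants, rose from 243 ± 12.8 to 976 ± 595 CPM (log2 fold change 1.98 ± 0.40, adjusted p = 0.00291). The other member, miR172, which targets AP2-like factors, was at 1344 ± 253 and 1026 ± 316 CPM and did not pass (-0.40 ± 0.33).

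Nutrient families went in both directions. In the phosphate and sulfate list, miR395, which targets ATP sulfurylase and a sulfate transporter, fell from 337 ± 91.0 to 114 ± 131 CPM (log2 fold change -1.92 ± 0.43), miR2111 rose (1.31 ± 0.36) and miR399 was at -0.70 ± 0.37. The miR2111 call ended with the standards as library size (adjusted p = 0.0886, edgeR), without pre-véraison 16 °C replicate 2 (0.0541) and without pre-véraison 38 °C replicate 1 (0.0948). None of the 3 copper families passed: miR397, which targets laccases, was at 0.15 ± 0.49, miR398, which targets copper superoxide dismutases, at -0.23 ± 0.41, and miR408 at 0.28 ± 0.41. The copper list's median was 0.15 while its set test pointed down (adjusted p = 0.948).

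No family of the MYB regulation list passed between stages. These 4 were miR159, miR319 (log2 fold change 0.31 ± 0.33), miR828 (0.52 ± 0.46) and miR858 (0.44 ± 0.33); miR828 and miR858 target MYB factors of the phenylpropanoid pathway. Of the 6 organ patterning families, miR164 fell, miR394 rose (1.25 ± 0.36) and 4 did not pass, among them miR166 (-0.12 ± 0.29), miR171 (0.60 ± 0.36) and miR396 (0.16 ± 0.33). That list's median was 0.02, its mean -0.32, and its set test pointed down (adjusted p = 0.901). With exact mature sequences in place of the family match, miR396 passed, at 1.51.

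Of the silencing machinery list, miR403 rose, while miR162, which targets DCL1, was at 0.26 ± 0.31 and miR168, which targets AGO1, at -0.68 ± 0.34. Without post-véraison 38 °C replicate 2, miR168 passed at -0.92 (adjusted p = 0.0473, edgeR). Among families that target NBS-LRR disease resistance genes, miR3633 fell (log2 fold change -1.56 ± 0.41) and miR482 was at 0.62 ± 0.32. miR169, which targets NF-YA factors, rose (1.196 ± 0.34). Of the list of families that respond to heat in other plants, 3 of 10 rose between stages and none fell.

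Passenger strands did not follow their guides throughout. The miR166 passenger fell from 3251 ± 588 to 1231 ± 1045 CPM (log2 fold change -1.54 ± 0.39, adjusted p = 0.00863, edgeR) while its guide, miR166, was at 1821 ± 157 and 1688 ± 368 CPM. With no CPM minimum the miR166 passenger did not pass (-1.24, adjusted p = 0.114, edgeR). The miR390 passenger rose (1.1999 ± 0.38), and those of miR168 and miR396 did not pass.

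The post-véraison 38 °C replicate 2 library stood apart from the other 3 post-véraison libraries in the families that fell. There, miR164 was at 154 CPM against 10.6 to 16.7, miR395 at 310 CPM against 37.6 to 63.1, and the miR166 passenger at 2798 CPM against 704 to 715. Fragments of the 18S rRNA 5′ end were at 47676 RPM in it, against 3847 to 9339. These values lay toward the pre-véraison libraries, and without this library 20267 sequences and 22 families passed between stages. The log2 fold changes were then -4.87 for miR164, -2.67 for miR395 and -2.16 for the miR166 passenger.

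**Figure D3:**
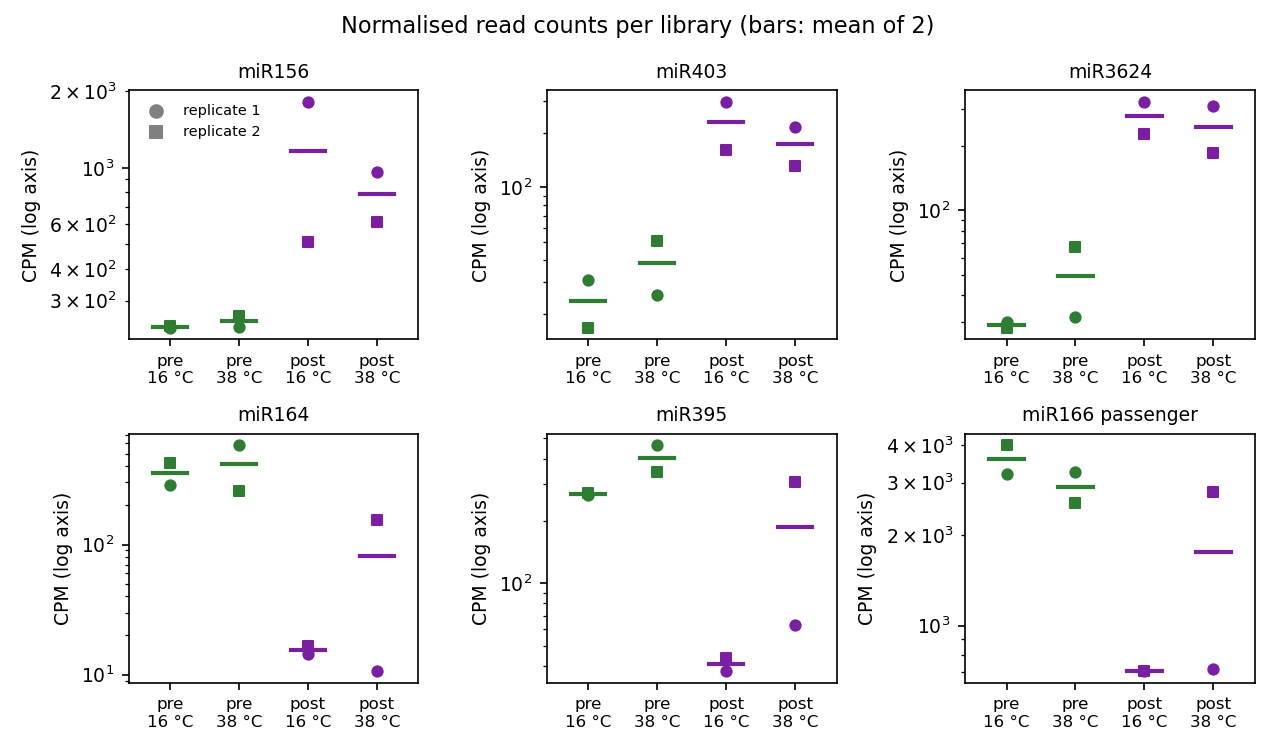
Normalised read counts (CPM, log axis) of 6 families or strands in each library, by stage and temperature (x axis); circles are replicate 1, squares replicate 2 and bars the mean of 2. For miR164, post-véraison 38 °C replicate 2 is at 154 CPM and the other post-véraison libraries at 10.6 to 16.7.

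Among single sequences, those of families included, 17582 of 42870 passed between stages, 8878 higher and 8704 lower after véraison (edgeR quasi-likelihood test, adjusted p under 0.05). Of these, 17521 were in no listed family. The direction went with length. Of 16286 sequences of 24 nt, 5484 fell and 2155 rose. Of 11710 sequences of 21 nt, 3218 rose and 1655 fell, and of 3145 of 22 nt, 836 rose and 302 fell. Set tests at the preset correlation gave adjusted p-values of 1.61e-08 for the fall at 24 nt, and 0.00721 and 0.00492 for the rises at 21 and 22 nt. With an estimated correlation these were an adjusted p of 0.264, 0.42 and 0.264, and without post-véraison 38 °C replicate 2 the rise at 21 nt did not pass (0.105). Among the 24-nt sequences outside the families, 46.7% of those beginning with G fell and 5.73% rose, against 26.8% and 21.1% of those beginning with A. The groups did not overlap for 33.5% of all sequences tested, where chance gives 2.86%.

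Total reads without TMM moved the median log2 fold change by 0.17, and the share of calls that were higher after véraison from 50.5% to 60.1%. With a single library left out, the number of sequences passing was lowest without pre-véraison 38 °C replicate 1 and highest without post-véraison 38 °C replicate 2. Between the stages at 38 °C alone, a contrast within the same model, 850 passed. That contrast holds post-véraison 38 °C replicate 2, which lay toward the pre-véraison libraries, so this count does not show an effect of heat on the stage difference.

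Named by the rule for largest changes, TGAACCCTCGTGATGGACGGC rose from 1.31 ± 2.62 to 57.9 ± 31.98 CPM (SD, n = 4), with reads in 1 of the 4 pre-véraison libraries. CTTCAACAGCTCACTACCGTC had 0 reads before véraison and 148 after it, at least 43.5-fold higher against a floor of 3 counts over the group. On the same floor, TTGGATGATGGAAAAACCAGCA was at least 22.9-fold, TGGTTAGGATATTCGGCT at least 22.6-fold and ACGCGGCTCTTGCCACCAGGTTGC at least 25.3-fold higher. Falling sequences were GCAAGAAAAAGGGCTTTGGGCGGG (from 9.61 ± 4.33 to 0.351 ± 0.702 CPM), TGGAACAAGCAGAAACAGAGAGAA (from 19.7 ± 6.67 to 1.91 ± 3.81 CPM) and GCCGAGATAATAAAGAGGAGC (from 13.1 ± 5.79 to 0.956 ± 1.84 CPM). GCTGATTAGCAAGAAAAAGGGC fell from 2.76 ± 2.28 to 0.0502 ± 0.1004 CPM, and CAAACGACGCTCGGCAACGG was at least 18.5-fold lower after véraison, with 49 reads before and 0 after. That last sequence differs by 1 base from the 5.8S rRNA 5′ end, so it may be an rRNA variant. Its call ended without pre-véraison 38 °C replicate 1, where the log2 fold change went from -6.16 to -5.58. Without pre-véraison 38 °C replicate 2, TGAACCCTCGTGATGGACGGC went from 8.17 to 11.87 on the log2 scale. Both are fitted values with 0 reads in most pre-véraison libraries, so neither is an exact fold. Without post-véraison 38 °C replicate 2, GCAAGAAAAAGGGCTTTGGGCGGG went from -6.50 to -9.24, TGGAACAAGCAGAAACAGAGAGAA from -6.33 to -10.27, GCCGAGATAATAAAGAGGAGC from -6.26 to -8.20 and GCTGATTAGCAAGAAAAAGGGC from -6.10 to -7.55.

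Among fragments of structural RNAs, which track RNA quality, no measure passed by stage after adjustment. Over 19 measures the adjusted p could hardly go under 0.05, since 4 against 4 gives no p below 0.0286. Equal RNA quality between the stages is therefore not shown. U6 snRNA fragments were at 80.5 ± 14.0 RPM before and 168 ± 49.97 after véraison, and fragments of the 5.8S rRNA core at 537 ± 80.2 and 989 ± 243 (SD, n = 4; exact permutation p = 0.0286 for both, adjusted p = 0.109 over 19 measures). Reads under 18 nt made up 6.43% ± 1.68 and 11.8% ± 1.91 of all reads, with the same p-values. These p-values also held for tRNA-Asp 5′ ends, at 918 ± 200 and 2118 ± 848 RPM, and for rRNA fragments as a class, at 880 ± 175 and 1761 ± 454 RPM. The 20-nt 18S rRNA 5′ end was at 63905 ± 31876 RPM before and 16528 ± 20895 after (exact permutation p = 0.0571). By temperature, no measure on the list passed, with adjusted p-values of 0.862 or more (exact permutation test). This test pooled both stages, so differences between the stages widened the spread it was set against. Equal RNA quality between the temperatures is not shown either.

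After 1 hour at 38 °C no miRNA family passed the test in either stage, on average over the stages, or in the interaction (edgeR, 0 of 39 in each). At an unadjusted p under 0.05 there were 1 family in pre-véraison berries, 3 in post-véraison berries, 2 on average and 1 in the interaction, and DESeq2 also called 0. Of the heat list from other plants, 0 of 10 passed in either stage, with median log2 fold changes of 0.23 and 0.24. miR398 was at 0.54 ± 0.59 (SE) in pre-véraison and 0.35 ± 0.59 in post-véraison berries, miR408 at 0.11 ± 0.58 and 0.26 ± 0.58, miR397 at 0.77 ± 0.70 and -0.36 ± 0.69, and miR156 at 0.08 ± 0.54 and -0.56 ± 0.54. miR159 was at -0.39 ± 0.43 and 0.62 ± 0.43, miR172 at 0.04 ± 0.46 and -0.28 ± 0.46, miR166 at -0.17 ± 0.42 and 0.43 ± 0.42, and miR168 at -0.61 ± 0.48 and 0.57 ± 0.48. miR396 was at 0.48 ± 0.47 and 0.19 ± 0.47, miR482 at 0.49 ± 0.45 and 0.15 ± 0.45, miR828 at 1.03 ± 0.69 and -0.36 ± 0.63, and miR858 at -0.04 ± 0.47 and 0.17 ± 0.47. miR395 was at 0.58 ± 0.59 and 2.19 ± 0.62, and passed in post-véraison berries without post-véraison 38 °C replicate 1 (log2 fold change 2.88, adjusted p = 0.0294), where the value rests on replicate 2, which stood apart. No list passed a set test for heat.

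Among single sequences, 28 passed for heat in pre-véraison berries (3 rose, 25 fell), 26 in post-véraison berries (6 rose, 20 fell) and 211 on average over the stages (117 rose, 94 fell). The balance of rises and falls depended on the scaling and the libraries. With the standards as library size, 9 of 271 rose in pre-véraison berries, 88 of 121 in post-véraison berries and 120 of 343 on average. In post-véraison berries 102 of 199 rose with the replicate number as a block, 158 of 187 without post-véraison 38 °C replicate 1, and 0 of 10 and 0 of 41 without post-véraison 16 °C replicates 1 and 2. On average, with single libraries left out, the share ran from 21 of 143 without post-véraison 16 °C replicate 2 to 374 of 509 without post-véraison 38 °C replicate 1. Most that fell within a stage were variants of rRNA and tRNA, whose sequences are not given: 17 of 25 before véraison and 19 of 20 after it, and 45 of the 94 on average. Without these variants, an alternative chosen after seeing the data, 0, 5 and 98 sequences passed. The named sequences outside the variants kept their fold changes, and those that no longer passed did so through the adjustment, over a table with fewer small p-values. In pre-véraison berries AGTTAATTCATGATCTGGC was at a log2 fold change of 5.07 ± 0.69 (SE) with and without the variants, with an adjusted p of 0.0139 and 0.0549 (edgeR). CCCTGTTGAGCTTGACTC was at -4.88 ± 0.66 in both, with the same adjusted p-values. Fragments of a 5.8S rRNA variant were at 621 ± 213 RPM at 16 °C and 58.4 ± 19.5 at 38 °C (SD, n = 4), 10.6-fold higher at 16 °C, whereas the main 5.8S form was at 39528 ± 7748 and 36850.0 ± 14463 (exact permutation p = 0.771). A 25S rRNA variant was 72.1-fold and a tRNA-Phe variant 44.0-fold higher at 16 °C, and a further tRNA variant 22.04-fold. A tRNA-Glu variant was 2.16-fold higher. The variants were chosen after their fall had been seen, so they are given as values without a test.

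Sequences that rose at 38 °C were rich in those ending in CCA, the 3 nt at the 3′ end of mature tRNAs, though none was matched to a tRNA. Of the 117 that rose on average, 59 ended in CCA (50.4%, against 1.77% of all sequences tested). Counted over all reads of 18 to 28 nt, those ending in CCA were at 8452 ± 128 RPM at 16 °C and 15748 ± 2553 at 38 °C (SD, n = 4), 1.86-fold higher, with 1.81-fold in pre-véraison and 1.91-fold in post-véraison berries. The same measure at 18 nt was 3.26-fold higher. It was chosen after the heat calls had been seen, so no test is given. Fragments from tRNA 5′ ends were at 10348 ± 3126 and 9217 ± 1568 RPM (exact permutation p = 0.629).

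**Figure D4:**
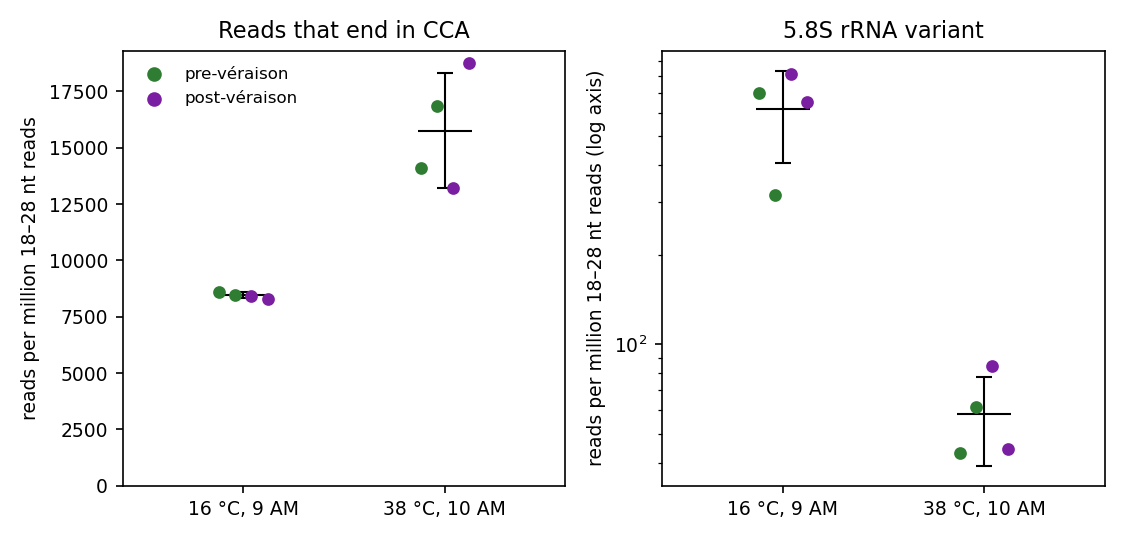
Reads that end in CCA (left, linear axis) and reads of a 5.8S rRNA variant (right, log axis), in RPM of 18 to 28 nt reads, in 16 °C and 38 °C libraries; points are libraries coloured by stage, and lines with bars are mean ± SD of 4. Reads ending in CCA lie at 8298 to 8609 at 16 °C and at 13222 to 18783 at 38 °C.

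Named rises at 38 °C were led by GGTTCAAATCCAGCTCGGCCCACCA, which ends in CCA and rose in both stages, from 0.761 ± 0.626 to 64.2 ± 54.9 CPM (SD, n = 2) before véraison, and at least 190.3-fold after it against 0 reads at 16 °C. In pre-véraison berries AGTTAATTCATGATCTGGC rose from 0.513 ± 0.125 to 16.7 ± 1.52 CPM and TATAGTTTGTTTGATGGTATC from 8.92 ± 2.27 to 156 ± 139 CPM. For the last, the log2 fold change went from 4.14 to 2.66 without pre-véraison 38 °C replicate 2 (adjusted p = 0.915, edgeR), and to 4.84 without replicate 1 of that group, and leaving out any other single library also ended the call. GGTTCAAATCCAGCTCGGCCCACCA, at 6.66 in pre-véraison berries, was at 7.55 and 5.72 without pre-véraison 16 °C replicates 1 and 2 in turn, and at 7.32 and 5.27 without the 38 °C replicates. In post-véraison berries its fitted value was 11.17, and 11.81 and 9.92 without 38 °C replicates 1 and 2 in turn. Against 0 reads at 16 °C these are no exact folds, and only the bound given above holds. In post-véraison berries the others were TTTTTTAGTTCTGAGGGAG (log2 fold change 6.63 ± 1.10 SE), TTCTCGGTGGAACCTCCA (4.83 ± 0.67) and AGTTTGTGGAGACCTGAACTGAAGAGC (4.31 ± 0.58). TTTTTTAGTTCTGAGGGAG was at 8.93 without post-véraison 16 °C replicate 2, and without post-véraison 38 °C replicate 2 it was at 5.65 and TTCTCGGTGGAACCTCCA at 3.95. On average over the stages TCTAGAAGTGTCAGAAGACTC, AGTTAATTCATGATCTGG, GACTTCCCCTGGGGGTACCA and GTTTTTAGTTCTGAGGGAGC also rose, by 5.57, 5.53, 5.51 and 5.47 on the log2 scale. Without post-véraison 38 °C replicate 2 the last 2 were at 4.31 and 4.39, and without post-véraison 16 °C replicate 2 at 6.65 and 7.28. TCTAGAAGTGTCAGAAGACTC was at 7.27 without pre-véraison 16 °C replicate 2. Its call ended without replicate 2 of the pre-véraison 38 °C, post-véraison 16 °C or post-véraison 38 °C group, at 5.41, 5.54 and 5.47. GGTTCAAATCCAGCTCGGCCCACCA, at 8.92, was at 8.21 and 8.28 without replicate 2 of the pre-véraison and post-véraison 38 °C groups. Named falls with a printed sequence were CCCTGTTGAGCTTGACTC (from 216 ± 111 to 7.33 ± 1.44 CPM) and TGTGGAATTGAACGCATTGAG (from 6.64 ± 2.94 to 0.275 ± 0.0733 CPM) in pre-véraison berries, and CGCAATGTGATTTCTGCCCA (from 20.6 ± 2.81 to 1.29 ± 1.11 CPM) in post-véraison berries. CCCTGTTGAGCTTGACTC went from -4.88 to -4.27 on the log2 scale without pre-véraison 16 °C replicate 1, and CGCAATGTGATTTCTGCCCA from -4.00 to -5.36 and -3.32 without post-véraison 38 °C replicates 1 and 2 in turn. Printed sequences were matched only to the lists of other RNAs, so some may be rRNA fragments that these lists lack. The named 19-nt rise before véraison and the named 18-nt rise on average equalled abundant 22-nt and 21-nt sequences with an inner run missing. These longer sequences had means of 18051 and 5987 CPM, and neither passed for heat within a stage. Their log2 fold changes at 38 °C were 0.48 and 0.47 before véraison, and -0.74 and -0.84 after it. The source of the shorter forms was not tested. Other named falls were of the variants: in pre-véraison berries the 5.8S variant of 26 nt was at least 21.8-fold, the tRNA-Phe variant of 19 nt at least 17.6-fold and the 25S variant of 22 nt 98.2-fold lower.

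Heat counts of single sequences changed with the libraries used. The 5 printed sequences called in pre-véraison berries all lost the call without either pre-véraison 38 °C library, and the 5 in post-véraison berries without either post-véraison 16 °C library or without post-véraison 38 °C replicate 2. With all deposited lengths these 10 calls ended too, as did those of the 5 printed sequences that rose on average over the stages. A lost call is not always a changed value, since one replicate was then left in a group: without pre-véraison 38 °C replicates 1 and 2 in turn, AGTTAATTCATGATCTGGC (5.07) was at 5.15 and 4.95, CCCTGTTGAGCTTGACTC (-4.88) at -4.69 and -5.12, and TGTGGAATTGAACGCATTGAG (-4.48) at -4.78 and -4.28. The libraries of the 2 temperatures did not overlap for 42.5% of sequences in pre-véraison berries and 31.5% in post-véraison berries, where chance gives 33.3%. With both stages pooled on each side, they did not overlap for 1.77%. The chance share of 2.86% holds only without a stage difference. Here that difference widened both sides, so the 1.77% cannot decide on heat. In simulated counts of heat averaged over stages, 18 of 144 calls were false, more than the threshold of 0.05 allows for. Without pre-véraison 38 °C replicate 1 or replicate 2, 0 passed in pre-véraison berries, without pre-véraison 16 °C replicate 1 there were 3, and without replicate 2 of that group 176. Without either post-véraison 16 °C library, 10 passed. In post-véraison berries 0 passed without post-véraison 38 °C replicate 2, 187 without post-véraison 38 °C replicate 1, and 10 and 41 without replicates 1 and 2 at 16 °C. On average over the stages the counts ran from 58 without pre-véraison 38 °C replicate 2 to 509 without post-véraison 38 °C replicate 1, with 67 without post-véraison 38 °C replicate 2. DESeq2 called 174, 162 and 467, and scaling by the standards moved the median log2 fold change by -0.57 in pre-véraison and by 0.26 in post-véraison berries.

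The heat effect was not found to differ between the stages in the main fit. Some sequences passed with no CPM minimum or with the standards as library size, as counted below. The standards moved the median log2 fold change of the interaction by 0.82. In the interaction 0 of 42870 sequences passed (edgeR), with 3432 at an unadjusted p under 0.05 and a smallest adjusted p of 0.618, and DESeq2 called 18. In simulated counts, interactions of 2-fold and 4-fold were recovered in 0% of cases, of 8-fold in 10% and of 16-fold in 36%, so that most differences of this size would be missed here.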

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

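The tests of explanations in this part, and the counts of other splits of the libraries, were written after the results they bear on had been seen. A library was singled out when its distance to the nearest of the 4 libraries of its stage exceeded, as a part of their range, Dixon's 95% critical value for 4 libraries. Of 116 such groups of 4, 13 held such a library, where chance gives about 1 in 20 (5.8), and 5 of the 13 were post-véraison 38 °C replicate 2.

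Post-véraison 38 °C replicate 2 was the highest of its stage for miR164 (154 CPM, the others 10.6 to 16.7), miR395 (310 CPM, the others 37.6 to 63.1), the miR166 passenger (2798 CPM, the others 704 to 715), 24-nt reads (32.1%, the others 26.1% to 27.0%) and 18S rRNA 5′ ends (47676 RPM, the others 3847 to 9339). On a scale from the other post-véraison libraries (0) to the pre-véraison ones (1), it had a median place of 0.446 (quartiles 0.234 to 0.676) over 641 sequences lower after véraison and of 0.598 (0.407 to 0.773) over 857 higher ones. The other heated post-véraison library had a median place of -0.0025 over the lower and 0.0996 over the higher sequences. These sequences were chosen with that library among the post-véraison ones, so its place cannot decide on heat. Over all tested sequences it correlated at 0.843 and 0.839 (Spearman) with the 16 °C post-véraison libraries, and at 0.684 with replicate 2, which was heated alike. Scaling is argued against by the ratio of the miR166 passenger to its guide within the library, 1.26 against 0.430 to 0.505. RNA of pre-véraison berries in post-véraison 38 °C replicate 2 may account for it, but the 4 medians by direction and length spread over 0.191, more than the 0.1 allowed for a plain mixture. That limit cannot decide either, since the 16 °C post-véraison libraries were themselves at -0.321 and 0.258 over the higher sequences. Such RNA and berries less advanced in ripening cannot be told apart here, since berries of intermediate stages were not among the libraries.

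Variants of rRNA and tRNA were higher in the 16 °C libraries than in the 38 °C libraries, and made up most sequences that fell with heat within a stage. A general fall of 5.8S fragments at 38 °C is argued against by the main form, at 0.932-fold, beside a variant that was 10.6-fold higher at 16 °C. RNA of another plant in the 16 °C libraries is a candidate explanation. Of 7 miRNAs known from legumes, 4 were read, with 23 reads, in all 4 of the 16 °C libraries, and 0 in the 38 °C libraries, although the 16 °C libraries held 43.5% of the depth. The 16 °C libraries had 2 to 11 such reads each; the list was written after the variants had been seen, so no p-value is given. No read of 3 grass or 2 Solanaceae miRNAs was found, Brassica miRNAs had 1 read at each temperature, and the plant the variants belong to was not determined.

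Reads that end in CCA were 1.86-fold higher at 38 °C. The listed 5′ tRNA fragments did not rise alike, at 0.891-fold, but they cannot decide on RNA breakdown of any kind. They were mostly tRNA-Ala (7533 of 9217 RPM at 38 °C), and pre-véraison 16 °C replicate 2 was high among them (14950.3 RPM). Fragments of tRNA-Asp of 29 to 35 nt were at 4859 ± 2218 and 13571 ± 17878 RPM, with 39783 in a single 38 °C library. A few abundant sequences are argued against by a rise that stayed at 1.86-fold without the 10 most abundant of each library. Heat, the hour of sampling (1.86-fold over both) and a step of handling that went with temperature cannot be told apart. The 10.6-fold difference in the 5.8S variant, whose source was not determined, may be a further difference between the 2 sets of libraries, which keeps this open.

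Splits of the libraries bear on whether chance can be excluded. Of 35 splits into 4 and 4, only 1, the real one, gave as many sequences by stage as 15613 in a model of stage alone; the highest other, 16 against 38 °C, gave 23. For families 1 of 35 gave 19, and the highest other 0. The other splits left the stage difference within both sides, so few calls were to be expected there. The real split ranked first for both stage counts, but 1 of 35 is the smallest share these libraries can give. Chance is therefore not excluded. For heat averaged over stages, 18 splits keep the stages balanced, too few for a share under 0.05. The real split gave 199 sequences and the highest other, replicate 1 against 2, 21 (1 of 18), and for families all 18 of 18 gave 0.

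Other libraries apart from their stage are given as values. Among pre-véraison libraries, miR156 was highest in 38 °C replicate 2 (262 CPM, the others 234 to 238), miR3624 in 38 °C replicate 2 (67.3 CPM, the others 28.1 to 31.8) and miR397 in 38 °C replicate 1 (334 CPM, the others 130.3 to 145). In the same stage 18-nt reads were lowest in 38 °C replicate 1 (1.08%, the others 1.67% to 1.77%) and 23-nt reads highest in 16 °C replicate 2 (6.40%, the others 5.58% to 5.65%). Fragments of tRNA-Asp were lowest in 16 °C replicate 1 (619 RPM, the others 1003 to 1040.2), and 5′ tRNA fragments highest in 16 °C replicate 2 (14950.3 RPM, the others 7555 to 8801).

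Signals in data outside the main tests were also seen. Longer fragments of tRNA-Asp, of 29 to 35 nt, were at 39783 RPM (of reads of all lengths) in post-véraison 38 °C replicate 1, against 1245 to 10052 in the other 7 libraries. Animal miR-1 had 89 reads over the 8 libraries, 70 of them in pre-véraison 16 °C replicate 1, and animal let-7a had 25, of which 11 were in that library. The legume miRNAs, with 23 reads, are described above.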

How the results depend on the processing

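Alternatives were fixed before the data were examined, except 3 chosen after seeing them: both doubtful libraries left out (pre-véraison 16 °C replicate 1 and post-véraison 38 °C replicate 2), the rRNA and tRNA variants left out, and the set tests without post-véraison 38 °C replicate 2. No named sequence, and no named family on a value past the threshold, changed direction under any alternative run. Families that did not pass crossed 0 under some: miR166, miR172, miR396, miR397, miR398, miR408 and miR828 by stage, and miR156, miR172, miR396, miR397, miR398, miR408, miR482, miR828 and miR858 for heat in one stage or both. Of 448 values of named families by stage, 436 kept their side of the threshold, 9 lost it (miR2950 and miR2111 in 3 alternatives each, miR3634 in 2 and the miR166 passenger in 1) and 3 gained it. Named sequences lost it in 1 of 173 values by stage, 58 of 138 for heat in pre-véraison berries, 48 of 156 in post-véraison berries and 17 of 170 on average. Shares of genome classes, with reads of a single place only as their alternative, were not run, since no reference genome was used. Where a library was left out of its group, the lone replicate was assumed to vary like the other groups. The causes were not tested, except that stricter count minimums and other lengths change the number of sequences tested.

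For sequences by stage (17582), the count was 11245 with the standards as library size, 3958 at 10 CPM, 38206 with no CPM minimum, 8719 with all deposited lengths, 11483 at 16 °C only, 850 at 38 °C only, and 7917 to 20267 with single libraries left out. For heat in pre-véraison berries (28) it was 271 with the standards, 14 at 10 CPM, 1709 with no CPM minimum, 0 with all lengths, 174 with DESeq2, 12 without both doubtful libraries, 0 without the variants, and 0 to 176 with single libraries left out. For heat in post-véraison berries (26) the same order gave 121, 17, 491, 0, 162, 16, 5, and 0 to 187. On average over stages (211) it gave 343, 51, 1120, 20, 467, 61, 98, and 58 to 509. For the interaction (0) there were 90 with the standards, 190 with no CPM minimum, 18 with DESeq2 and 0 to 10 with single libraries left out. Families by stage (19) numbered 11 with the standards, 4 at 38 °C only and 12 to 22 with single libraries left out, and families for heat in post-véraison berries and on average 0 to 2. Set tests by stage passed 5 of 13 lists, 0 with an estimated correlation and 3 without post-véraison 38 °C replicate 2.

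The replicate number as a block gave 17672 sequences by stage, 163 and 199 for heat in pre-véraison and post-véraison berries, 613 on average and 2 for the interaction. Deviations of same-numbered libraries correlated from -0.187 to 0.323 over the 6 pairs of groups. The highest, 0.323, was between the 16 °C and 38 °C groups of post-véraison berries, while that of pre-véraison berries was -0.0631. The main fit did not take the numbers as pairs. A link between same-numbered post-véraison libraries is not excluded, and the heat counts depend on this choice. The block changed no other count by over 1.5 times. It ended the set-test call of all 35 families together by stage (adjusted p = 0.0536, camera), leaving 4 of 13 lists.

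Size shares by stage kept their direction: the 21-nt difference ran from 5.01 to 8.27 points and the 24-nt one from -11.5 to -9.06 with single libraries left out, where 4 against 3 cannot give a p below 0.0571. Depth limits families such as miR3627 and miR390, near 1 CPM before véraison.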

Other observations

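The sequences and ratios in this part were chosen after their values had been seen, because they differed, so the ratios are given as values without a test. In some families the members did not change alike. In miR156, TTGACAGAAGATAGAGAGCAC rose from 122 ± 21.2 to 847 ± 516 CPM (SD, n = 4; log2 fold change 2.77 ± 0.42 SE), whereas TGACAGAAGAGAGTGAGCAC was at 92.7 ± 12.2 and 57.4 ± 27.8 CPM (-0.73 ± 0.36, adjusted p = 0.11 in edgeR). In miR169, TGAGCCAAGGATGACTTGCCG rose (1.01 ± 0.37) and CAGCCAAGGATGACTTGCCGG fell (-1.54 ± 0.43). In miR160, TGCCTGGCTCCCTGTATGCCA rose from 5.37 ± 3.41 to 38.7 ± 6.73 CPM, and TGCCTGGCTCCCTGAATGCCA was at 3.09 ± 1.29 and 4.09 ± 1.37 CPM. In miR396, TTCCACAGCTTTCTTGAACTG rose from 18.1 ± 3.97 to 51.0 ± 18.6 CPM.

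The ratio of the first miR156 member to the second was 1.35 ± 0.397 (SD, n = 4) before and 15.2 ± 7.37 after véraison, and that of the miR169 members 1.01 ± 0.455 and 8.12 ± 6.35. The ratio of the miR166 passenger to its guide was 1.78 ± 0.185 and 0.669 ± 0.398. For the miR166 pair, post-véraison 38 °C replicate 2 was at 1.26, between the other 3 post-véraison libraries and the pre-véraison ones.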
